A study of Mus musculus with 2 samples.

How the data were processed

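Gene expression was measured by 10x Visium in 1 WT and 1 NFYa cKO section of embryonic day 15.5 mouse heart, frozen in embedding medium, sectioned at 10 µm and permeabilized for 18 min. The deposited values are UMI counts per gene and spot, made by the authors with Space Ranger (version not given) against GRCm38 (mm10), in matrices filtered to spots under tissue. The matrices hold 32285 genes, named by the symbol and Ensembl identifier they give. For 38 symbols listed under more than 1 identifier the first was used, and 5 symbols of the preset lists (Atp5pb, Ctgf, Cyr61, Zac1, Ahsp) were not in the matrices. Gene positions came from a RefSeq table for GRCm38.p6 in which 26335 symbols matched. Spot positions and images were not used, and introns, exons and strain variants were not examined, so no tag was placed within Nfya.

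UMIs were summed over the spots of a section or region and divided by all UMIs of those spots to give CPM, with exact Poisson 95% intervals. The ratio of NFYa cKO to WT has an exact conditional binomial (Clopper-Pearson) 95% interval. Depth was 9140052 and 12084511 UMIs, at which a count of 0 allows up to 3 counts. Since each genotype has 1 section, no test, p-value or number of changed genes was computed. Members of a list were counted at ratios of 1.25 or more and 0.8 or less. The share of all genes at these sizes is not given, so the counts describe the lists only. A list's median log2 ratio was taken over members with 20 or more UMIs in both sections together, with an interval from 1000 Poisson draws of its counts, and placed among 10000 random lists drawn from 20 expression bins. Genes are named by a rule: Nfya, the 12 highest and 12 lowest ratios among genes with 100 or more UMIs by the interval bound nearest to 1, and in each list the member with the most UMIs and up to 3 with the largest log2 ratios, with further list members named to describe a list. Some genes that this rule names are not reported.

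Spots of both sections were clustered on 113 genes of 19 anatomical marker lists: log counts per 10000, each gene scaled within its section, 15 principal components, 15 nearest neighbours and Leiden at resolution 1, which gave 8 regions. Because scaling was within section, region sizes are not a comparison of genotypes. Regions are described by their 10 leading genes by fold of CPM inside over outside the region. Both sections were pooled for this, so a leading gene need not mark its region in each section. No region was led by ventricular markers under the preset rule, so the 3 regions with Myl2, Myh7 and Irx4 each above the section's own mean in both sections, called Myl2-rich, took the place of ventricular spots.

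The 33 gene lists, the marker lists, the naming rule, the scalings and 16 alternatives were fixed before the data were examined. Alternatives were scaling without mitochondrially encoded and haemoglobin genes, centring on the median gene, the mean of spot CPM, removal of spots with fewer UMIs than their section's median divided by 3, equal region makeup, other UMI minimums and other ways to choose the Myl2-rich spots. The rule for Myl2-rich regions, 4 added lists (granulocyte, activated macrophage, mast cell, and myocardin-SRF and YAP responsive genes) and 3 added alternatives (equal makeup of the Myl2-rich regions, all regions with Myl2 above the section mean, and list members without clustering genes) were chosen after seeing the data.

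The steps were tested on simulated data made from the summed counts. Of 10908 genes, 200 were given known folds, and intervals held the true fold for 95.4% of the 10708 genes at fold 1 and for 94%, 92%, 96% and 94% of genes at folds of 0.5, 0.8, 1.25 and 2. Intervals excluded 1 for 96%, 56%, 72% and 100% of these, and for 4.57% of genes at fold 1. With the G2/M list simulated at fold 0.7, the median was at -0.51 for a true -0.51, and 20 of 20 intervals held it. At fold 1, 20 of 20 intervals held 0, with percentiles from 3.31 to 99.63. Simulation has counting error only. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.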

Results

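Spatial transcriptomes were measured by 10x Visium on coronal four-chamber sections (10 µm) of E15.5 C57BL/6 mouse hearts. There was 1 section from a wild-type (WT) heart and 1 from a heart labelled NFYa cKO, a conditional knockout of Nfya. Nfya encodes the DNA-contacting subunit of NF-Y, a factor that binds CCAAT boxes in the promoters of many cell-cycle and metabolic genes. The series title names the metabolism and the proliferation of fetal heart muscle cells as the question. The WT section had 373 spots with 9140052 unique molecular identifiers (UMIs), and the section labelled NFYa cKO had 333 spots with 12084511. Median depth was 23912 and 36500 UMIs per spot, with medians of 5823 and 6797 genes per spot. Mitochondrially encoded genes took 3.47% of UMIs in WT and 4.72% in the section labelled NFYa cKO, and haemoglobin genes took 5.22% and 3.49%. With 1 section per genotype there was no replicate spread and no test. Intervals are 95% intervals from the counts and cover counting error only. Every ratio below is the level in the section labelled NFYa cKO over that in WT, and a spot covers several cells.

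Nfya itself was higher, not lower, in the section labelled NFYa cKO, and every direction given below rests on the label. Nfya (ENSMUSG00000023994, GRCm38 chromosome 17, 48386885 to 48409820) had 291 UMIs in WT, 31.8 CPM (counts per 1e6 UMIs, interval 28.3 to 35.7). It had 700 UMIs in the section labelled NFYa cKO, 57.9 CPM (53.7 to 62.4), a ratio of 1.82 (1.58 to 2.09). The labels do not say which part of the gene was deleted, and 3′ tags may lie outside that part, in which case they check nothing about the deletion. Nfyb, which encodes a histone-fold partner of Nfya, had a ratio of 1.41 (1.21 to 1.66), and Nfyc, the other partner, a ratio of 0.882 (0.806 to 0.966). Sp1, Sp2 and Sp3, whose GC-box sites often lie beside CCAAT boxes, had ratios of 0.815, 1.11 and 1.05. The median log2 ratio of these 6 genes was 0.11.

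The first comparison asked how genes of proliferation and metabolism differed between the whole sections. Most genes of mitosis were lower in the section labelled NFYa cKO, with the cytokinesis gene Kif23 and the spindle gene Ckap2 lowest, and 13 of 29 DNA replication genes were lower, among them Tk1 and Pcna. Of the fatty acid oxidation genes 11 of 25 were lower, with the acyl-CoA synthetase Acsl1 and the mitochondrial regulator Ppargc1a lowest, and of calcium handling and ion channel genes 12 of 22, such as Hrc and Kcnq1. Most genes of cardiac wall stress were higher, among them the natriuretic peptide gene Nppb and the fetal actin gene Acta1, and so was the cell-cycle inhibitor Cdkn1a. Each list below was compared with 10000 random lists matched for expression, and percentiles among them describe these libraries only. The median log2 ratio of the 10908 genes with 100 or more UMIs was -0.10, a second reference beside the random lists.

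The G2/M and mitosis list had a median log2 ratio of -0.49 (-0.54 to -0.44), below all 10000 random lists. Of its 40 genes, 32 were lower (a ratio of 0.8 or less) and 0 were higher (the inverse of that ratio or more). Kif23 and Racgap1, which act in cytokinesis, had ratios of 0.517 and 0.582, and the spindle gene Ckap2 had 0.564. Mki67, a marker of cycling cells, was at 128 CPM in WT and 82.3 CPM in the section labelled NFYa cKO (ratio 0.642, 0.590 to 0.699). The DNA topoisomerase gene Top2a had a ratio of 0.719 and the mitotic kinase gene Cdk1 0.781. Hmgb2, a chromatin protein gene with the most UMIs in the list, had a ratio of 0.845. The DNA replication and G1/S list had a median of -0.28 (-0.37 to -0.24), at percentile 0.33, with 13 of 29 genes lower and 2 higher by the same sizes. Tk1, which makes thymidine monophosphate, had a ratio of 0.560, the replication protein gene Rpa2 0.632, the primase gene Prim1 0.685 and the sliding clamp gene Pcna 0.750. The 2 higher genes were the D-type cyclin genes Ccnd1 (1.34) and Ccnd2 (1.30), which act upstream of S phase. The p53 response list had a median of 0.45 (0.27 to 0.52; 0.29 as the mean of spot CPM), with 13 of 21 genes higher and 4 lower. Cdkn1a, the inhibitor of cyclin-dependent kinases, was at 26.2 and 88.9 CPM (ratio 3.40, 2.95 to 3.93). The ectodysplasin receptor gene Eda2r had a ratio of 9.27 and Phlda3, an inhibitor of Akt, 2.03, whereas Mdm2, which targets p53 for degradation, had 1.07 and the desmosomal gene Perp 0.626. The histone list, which includes replication-dependent and variant genes, had a median of 0.23 with 12 of 26 genes higher and 6 lower. Its median was below 0 when genes with 1 UMI in each section were admitted.

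Among metabolic genes, the fatty acid oxidation list had a median of -0.30 (-0.35 to -0.25), below all 10000 random lists, with 11 of 25 genes lower and 0 higher. Acsl1, which activates long-chain fatty acids, had a ratio of 0.348 (0.310 to 0.390), and Ppargc1a, a coactivator of mitochondrial genes, 0.356 (0.306 to 0.415). The lipoprotein lipase gene Lpl had a ratio of 0.618, the thiolase gene Acaa2 0.645 and the fatty acid carrier gene Fabp3 0.839. The TCA cycle list had a median of -0.20 (-0.10 after centring on the median gene), with 3 of 21 genes lower, 0 higher and 18 between, among the lower Idh2 (isocitrate dehydrogenase) at 0.667 and Pdhb (pyruvate dehydrogenase) at 0.713. The 73 nuclear genes of the respiratory chain and ATP synthase had a median of -0.12, below all random lists but near the median of all genes, with 7 lower and 1 higher, while the muscle isoform genes of cytochrome c oxidase Cox6a2 and Cox7a1 had ratios of 0.404 and 0.567. The 13 mitochondrially encoded genes went the other way, with a median of 0.47 (0.45 to 0.48) and 11 higher, including mt-Nd2 at 1.46 and mt-Co1 at 1.29. The glycolysis list had a median of -0.07, with 4 of 20 genes higher and 4 lower. The lactate transporter gene Slc16a1 (2.05) and the glucose transporter gene Slc2a1 (1.78) were higher, and Ldhb (lactate dehydrogenase, 0.548) and Pfkm (phosphofructokinase, 0.620) were lower. Fatty acid synthesis had a median of -0.26 over 11 genes and cholesterol synthesis 0.13 over 23. Serine and one-carbon metabolism was at -0.12, and medians lay within 0.1 of 0 for the mitochondrial ribosome (-0.09), mitochondrial chaperones (-0.07), purine and pyrimidine synthesis (0.01), cytosolic ribosomal proteins (0.02) and the hypoxia response (-0.03).

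Cardiac stress genes had a median of 1.37 (1.27 to 1.49), above all random lists, with 12 of 14 genes higher and 2 lower. Nppb, the B-type natriuretic peptide gene (GRCm38 chromosome 4, 147985786 to 147987205), was at 185 and 1556 CPM (ratio 8.43, 8.02 to 8.87). Nppa, the atrial peptide gene, was at 7573 and 14646 CPM, a ratio of 1.93. Acta1, the skeletal actin gene expressed in fetal and loaded myocardium (chromosome 8, 123891758 to 123894775), had a ratio of 15.8 (14.4 to 17.4), a log2 ratio of 3.98, and a log2 ratio of 3.47 as the mean of spot CPM. The stretch-responsive gene Ankrd1 had a ratio of 3.17, the secreted factor gene Gdf15 7.70 and Clu, an extracellular chaperone gene, 2.64. The 2 lower members were the metallothionein genes Mt1 (0.553) and Mt2 (0.702), which bind zinc and copper. The integrated stress response list had a median of 0.35, with Atf3 at 2.25 and the asparagine synthetase gene Asns at 2.01. The endoplasmic reticulum chaperone list had a median of 0.18 (0.05 as the mean of spot CPM), with the folding factor genes Creld2 at 2.45 and Pdia6 at 1.96, and the cytosolic heat shock list 0.29, with the small chaperone gene Hspb1 at 500 and 1448 CPM (ratio 2.89). Immediate early genes had a median of 0.41, with Fos at 3.01, Egr1 at 2.26 and the flow-responsive gene Klf2 at 0.521. The interferon list had a median of 0.19 over 10 genes and the 4 nuclear noncoding RNAs 0.12, among which Neat1 had a ratio of 3.29.

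Calcium handling and ion channel genes had a median of -0.55 (-0.59 to -0.42), below all random lists, with 12 of 22 genes lower and 0 higher. Hrc, whose product binds calcium in the sarcoplasmic reticulum, was at 69.4 and 18.1 CPM (ratio 0.261, 0.223 to 0.305). The reticulum pump gene Atp2a2 was at 1897 and 1161 CPM (ratio 0.612), and the potassium channel gene Kcnq1 had a ratio of 0.408. Kcnj3 (0.305), a channel of atrial muscle, and Hcn4 (0.361), a channel of pacemaker cells, were also lower. The exchanger gene Slc8a1 and the connexin gene Gja1 had ratios of 1.21 and 1.19, and Ryr2, the calcium release channel gene, 1.01. The sarcomere list had a median of 0.22, and 0.12 with both sections weighted to the same region makeup, with 13 of 31 genes higher and 5 lower. The intermediate filament gene Des (2.59), the Z-disc gene Myoz2 (2.55), Nrap, which acts in myofibril assembly (2.39), and the mechanosensor gene Csrp3 (2.12) were higher, and the cardiac actin gene Actc1 had a ratio of 1.57. The atrial-rich myosin genes Myh6 (0.512) and Myl7 (0.543) and the M-band gene Myom2 (0.601) were lower. Cardiac transcription factors had a median of 0.02 with 7 of 24 higher and 6 lower. Compact-layer genes had a median of 0.18 (0.05 as the mean of spot CPM), with Hey2, a Notch target, at 0.640. Trabecular genes had a median of 0.51 (0.14 at equal region makeup), with the growth factor gene Bmp10 at 2.58 and Cpne5 at 0.339. Some preset lists share members, so their medians are not separate: Acta1 and Xirp2 are in the sarcomere and stress lists, and Nppa and Nppb in the stress and trabecular lists. Growth factor and receptor genes had a median of 0.17 (from 0.07 to 0.27 over the alternatives), with Hbegf (5.15) and Nrg1 (4.22), both ligands of ErbB receptors, and Igf1r (1.67) higher. Imprinted growth genes had a median of 0.05, with Mest at 2.02 and Dlk1 at 0.457.

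**Figure D1:**
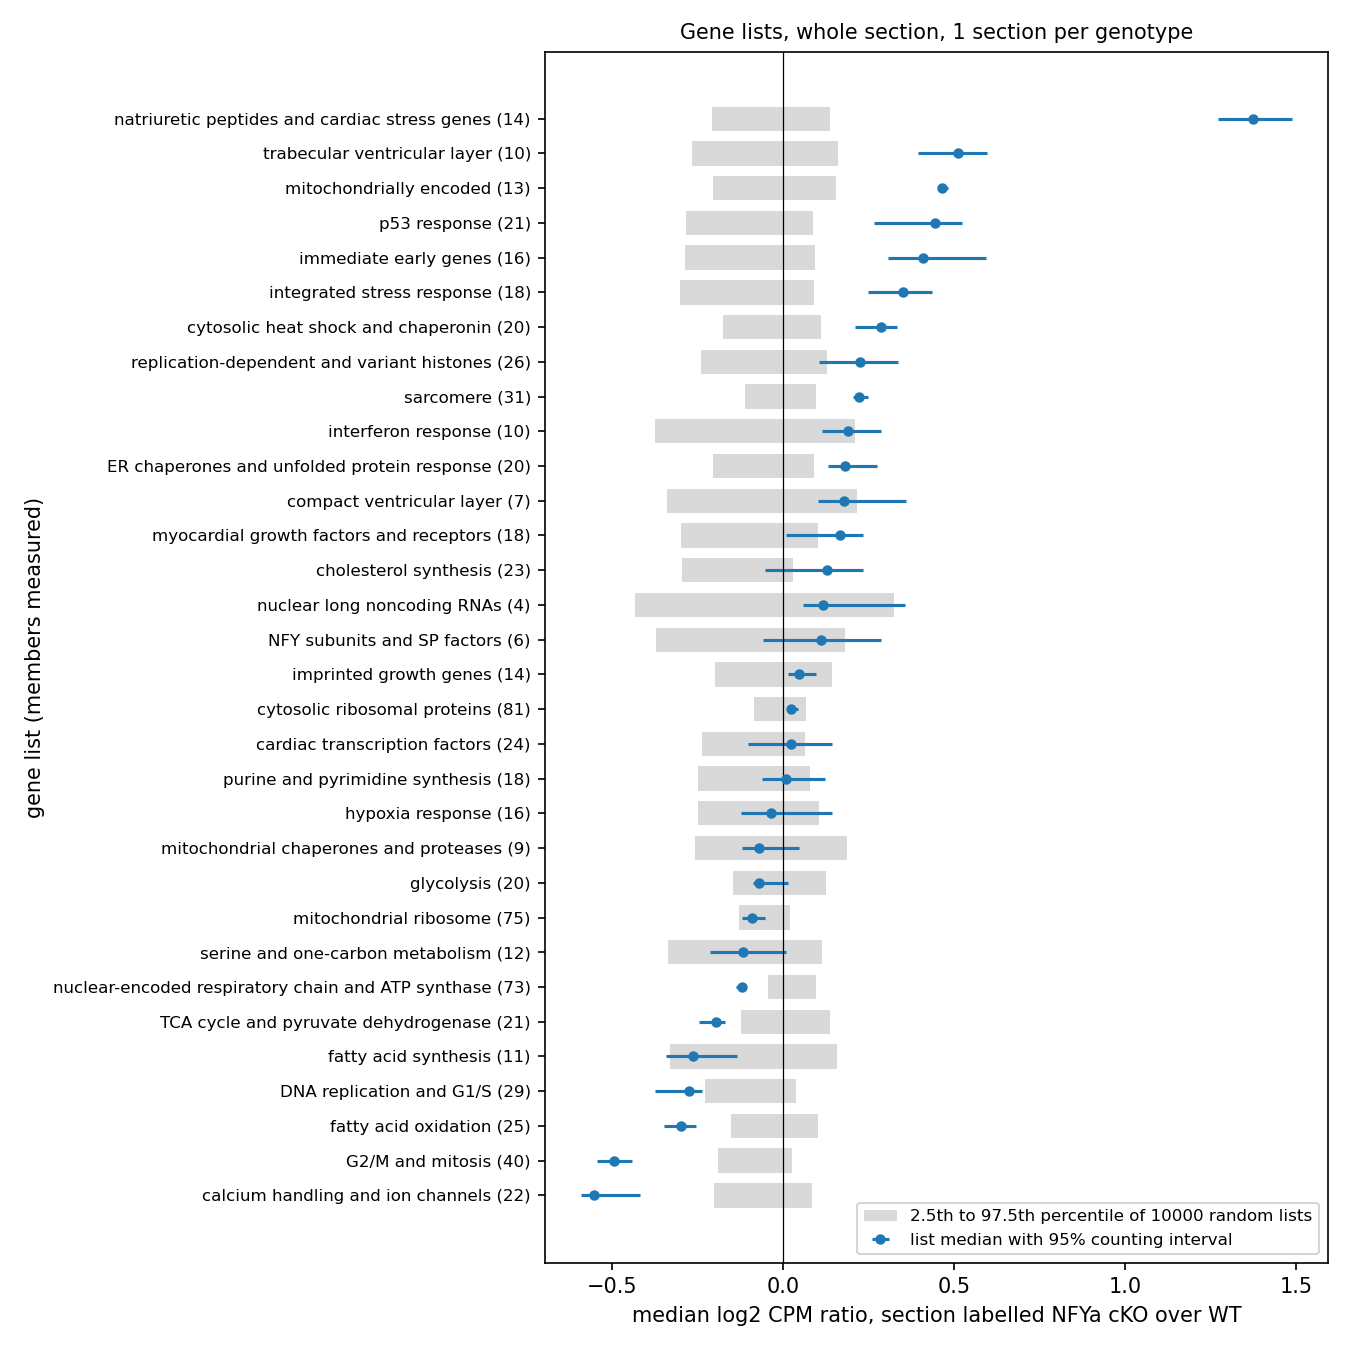
Median log2 ratio of each gene list, NFYa cKO over WT, with its 95% interval from the counts and the range of random lists matched for expression. The G2/M list sits at -0.49 and the cardiac stress list at 1.37 in the whole section.

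Among single genes with 100 or more UMIs, those farthest from a ratio of 1 by the near bound of the interval included members of the lists and other genes. Sprr1a, which encodes a cornified-envelope protein, was at 0.547 and 21.3 CPM (ratio 38.9, 16.4 to 121). Xirp2, an actin-binding gene of intercalated discs, was at 2.74 and 49.3 CPM (ratio 18.0, 12.1 to 28.1). The carboxypeptidase gene Cpa4 had a ratio of 22.4 and the kinase gene Bcr 9.26. Ccn2, a matricellular gene, had a ratio of 9.69 (8.95 to 10.5), and Tagln, an actin-bundling gene, 8.99 (8.41 to 9.63). Krt17, a keratin gene, had 2 and 103 UMIs (ratio 39.0, 10.5 to 326), the macrophage elastase gene Mmp12 had 3 and 118 (ratio 29.8, 9.93 to 146), and the histone gene Hist1h4h had a ratio of 12.8. Cstdc4, a stefin gene with near-identical neighbours, had 0 UMIs in WT and 107 in the section labelled NFYa cKO. That is 27.0-fold higher with WT set at the floor of 3 counts per section, and the interval of its ratio starts at 21.6. Lower genes included Agtr2, the angiotensin receptor type 2 gene, with 225 and 2 UMIs (ratio 0.00672, 0.000809 to 0.0246). The ephrin receptor gene Epha3 had a ratio of 0.0921, the T-cell receptor constant gene Trac a log2 ratio of -3.32, the sinus-venosus factor gene Shox2 a ratio of 0.135 and the secreted factor gene Gdf10 0.159. Several of these genes were local in WT. Region 2 of the clustered regions held 90 of 123 Shox2 and 85 of 121 Trac UMIs, and regions 2 and 5 held 77 and 88 of the Agtr2 UMIs. Region 2 had 73 spots in WT and 43 in the section labelled NFYa cKO. Ratios within region 2 were 0.155 (Shox2), 0.0411 (Trac) and 0.129 (Gdf10), and makeup was not separated from expression. Kcnip2, a subunit of the transient outward potassium channel, had a ratio of 0.168, Perm1, a muscle regulator of mitochondrial genes, 0.177, the leucine-rich repeat gene Lrrc14b 0.190 and the phosphatase inhibitor gene Ppp1r1b 0.194. Gm21860 (0.0469), Gm8113 (0.0837) and Gm47547 (0.120) are predicted genes with near-identical copies, so their tags may be exchanged.

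Marker lists of cell types and tissues also differed between the sections, and whether makeup or expression within a tissue differed was not separated. The atrial list had a median of -0.84 with 9 of 10 genes lower, including Sln (0.421), a regulator of the calcium pump, and the transcription factor gene Nr2f1 (0.284). With both sections weighted to the same region makeup its median was -0.50. The fibroblast list had a median of -0.62 with 8 of 11 lower, including the collagen gene Col1a1 at 1202 and 690 CPM, and a median of -0.35 at equal makeup. The coronary endothelial list was at -0.41, the Schwann cell and neuron list at -0.58 (-0.32 at equal makeup) and the erythroid list at -0.53 (-0.33 at equal makeup). Macrophage and leukocyte genes had a median of 0.64 with 10 of 12 higher, including the lysozyme gene Lyz2 at 4.02 and the adaptor gene Tyrobp at 2.41, while Mrc1, a receptor of resident macrophages, had 0.554. The endocardial list had a median of 0.22 (0.09 at equal makeup), with the endothelin gene Edn1 at 3.18, and the epicardial list 0.18 (0.66 at equal makeup), with the keratin gene Krt19 at 4.63. Ventricular markers had a median of 0.14 and -0.10 at equal makeup, smooth muscle 0.10 (0.28 at equal makeup), pan-endothelium -0.03, with the sialomucin gene Emcn at 2.66, valve mesenchyme -0.09 (-0.28 at equal makeup) and platelets 0.14. Lists of tissues next to the heart had few measured genes: skeletal muscle (5 genes, -0.07), cartilage (4, -0.09), liver (3, 0.01), adipose tissue (2, -0.09), lung and airway epithelium (1, 1.01) and thymus (1, -0.37). The 1 gene of the lung list was Krt8, also a leading gene of region 8 beside the mesothelial genes Upk1b and Msln, so its value does not measure lung. Both embryos were male by these genes: Xist had 0 UMIs in each section, and the Y-linked gene Eif2s3y had 607 in WT and 695 in the section labelled NFYa cKO. The embryo sex list had a median of -0.15.

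**Figure D2:**
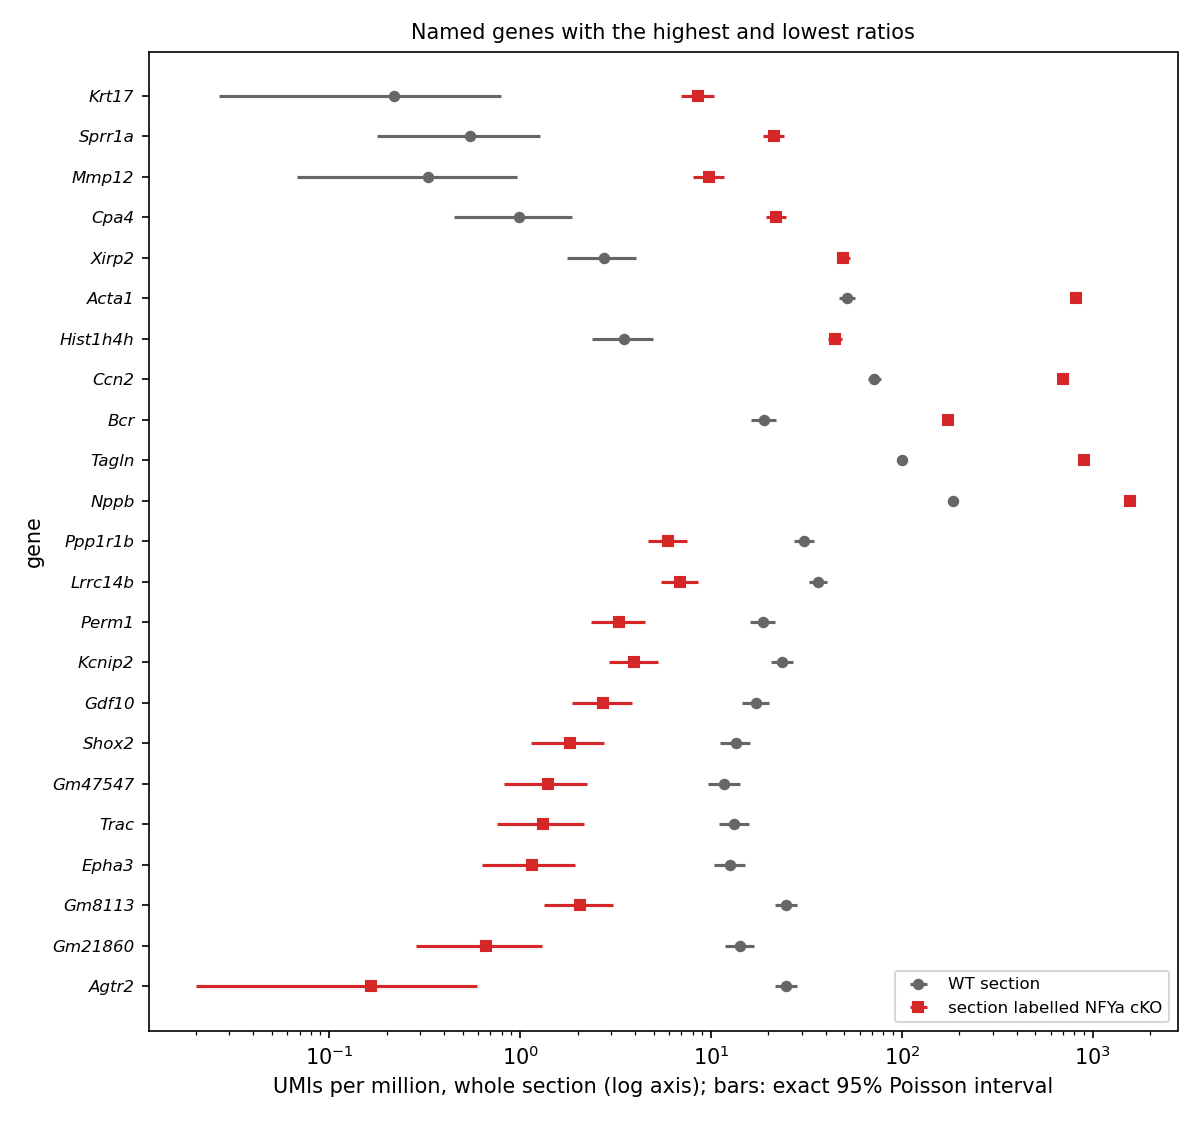
CPM in each whole section, with exact 95% Poisson intervals on a logarithmic axis, of the genes with the highest and lowest ratios by the near bound of the interval, without Cstdc4, which had 0 UMIs in WT. Nppb sits at 185 CPM in WT and 1556 CPM in the section labelled NFYa cKO, and Agtr2 had 225 and 2 UMIs.

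The second comparison took spots rich in ventricular muscle genes, because heart muscle is the tissue in which the series title places the question. Clustering of spots on preset anatomical markers gave 8 regions, and regions 1, 3 and 6 had the ventricular genes Myl2 (8816 to 9727 CPM), Myh7 and Irx4 above the mean of their section in both sections. Most fatty acid oxidation genes were lower in these Myl2-rich regions, 13 of 21 TCA cycle genes were lower, and 12 of 14 stress genes were higher. G2/M genes had a median of -0.53, and of -0.31 when the regions were given equal makeup. The regions held 83, 33 and 41 spots in WT (3230432 UMIs) and 65, 75 and 28 in the section labelled NFYa cKO (5864593 UMIs), so region 3 weighed more in the latter. Leading genes of region 3 (Xirp2, Sprr1a, Cpa4, Bcr, Spp1 and Ccl2) were themselves among those that differed between the sections. They were ranked with both sections pooled. In WT, region 3 held 0 Sprr1a UMIs, and Bcr was at 21.45 CPM there against 18.93 in the whole section. Xirp2 was at 7.57 against 2.74 CPM in WT. The median log2 ratio of all 8801 genes with 100 or more UMIs was -0.12 here. Single genes used for the clustering are not compared within regions, but some lists contain them. Cell-type lists used for the clustering differed within these spots too, with medians of 1.62 for macrophages and leukocytes, 0.70 for smooth muscle, -0.61 for coronary endothelium and -0.56 for atrial muscle, so marker levels were not held equal.

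Nfya was at 32.2 and 51.7 CPM in the Myl2-rich regions (ratio 1.60, 1.28 to 2.02). It was again higher in the section labelled NFYa cKO, which does not check the deletion. G2/M genes had a median of -0.53 (-0.59 to -0.44) with 31 of 40 lower. Mki67 was at 169 and 99.4 CPM (ratio 0.587, 0.522 to 0.661), and Top2a had a ratio of 0.681. G1/S genes had a median of -0.34 (-0.45 to -0.27), and -0.19 at equal makeup, with 16 of 29 lower and 3 higher, with Tk1 at 0.490, Pcna at 0.710 and Ccnd1 at 1.35. The p53 response list had a median of 0.28 (0.01 to 0.42; 0.14 as the mean of spot CPM) with 10 of 20 higher and 5 lower, and Cdkn1a had a ratio of 2.30. The fatty acid oxidation list had a median of -0.54 (-0.59 to -0.50), with 21 of 25 genes lower and 1 higher. Acsl1 was at 173 and 43.8 CPM (ratio 0.253, 0.218 to 0.294), Ppargc1a at 76.2 and 20.6 CPM (ratio 0.271), and the medium-chain dehydrogenase gene Acadm, the lipase gene Lpl and Fabp3 had ratios of 0.561, 0.496 and 0.685. Acot1, which releases free fatty acids from acyl-CoA, had a ratio of 0.223. The TCA cycle list had a median of -0.42 with 13 of 21 genes lower and 0 higher, nuclear respiratory genes -0.23 with 21 of 73 lower, and the mitochondrial ribosome -0.18 with 16 of 75 lower. With clusters of variable genes the medians of these respiratory and ribosome lists were -0.12 and -0.11, and after centring on the median gene -0.11 and -0.05. Mitochondrially encoded genes again went the other way, at 0.47. Glycolysis had a median of -0.21 (-0.07 at equal makeup) with 4 of 20 higher and 7 lower, and cholesterol synthesis 0.33 (0.52 at equal makeup) with 12 of 23 higher and 4 lower.

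Stress genes had a median of 2.10 (1.93 to 2.27) in the Myl2-rich regions. Nppb was at 106 and 1705 CPM (ratio 16.1, 14.5 to 18.0), Nppa at 3290 and 13440 CPM, Acta1 at 37.8 and 1050 CPM (ratio 27.8, 23.3 to 33.6) and Ccn2 at 39.6 and 814 CPM (ratio 20.5, 17.2 to 24.7). The log2 ratio of Acta1 here was 4.80, and 3.41 as the mean of spot CPM, in which each spot weighs the same. Those of Nppb and Ccn2 were 4.01 and 4.36, and 3.61 and 4.05 at equal makeup of the Myl2-rich regions, below their intervals. Ankrd1 had a ratio of 5.67, Gdf15 12.9 and Mt1 0.425. Xirp2 had a ratio of 29.9, Bcr 14.2, the keratin gene Krt18 13.8 and the chemokine gene Ccl2 11.8. Sprr1a had 1 and 170 UMIs, a ratio of 93.6 (16.6 to 3720), Cpa4 had a ratio of 78.2 (13.8 to 3111) and the unnamed transcript 4930478M13Rik 17.6. Integrated stress response genes had a median of 0.51 with 13 of 17 higher, heat shock genes 0.38 with Hspb1 at 3.60, and immediate early genes 0.61. Calcium handling and ion channel genes had a median of -0.58 (-0.67 to -0.43) with 12 of 22 lower and 0 higher, and -0.40 over the members not used for clustering. Atp2a2 had a ratio of 0.510, Hrc 0.303 and Kcnq1 0.327. The sarcomere list had a median of 0.25, and 0.40 without clustering genes. Genes with low ratios were the reductase gene Dhrs7c (0.0838, a log2 ratio of -3.58, but -2.68 in spots with Myl2 above the section median), Kcnip2 (0.110), Lrrc14b (0.115), Perm1 (0.115), the mitochondrial creatine kinase gene Ckmt2 (0.197) and the slow myosin gene Myh7b, at 210 and 45.5 CPM (0.217). The RNA-binding gene Ybx2 (0.174), Ppp1r1b (0.201), the retinol-binding gene Rbp7 (0.215) and the ubiquitin ligase subunit gene Asb11 (0.255) completed the 12 named as lowest, with Acsl1 and Acot1.

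Within single regions, numbered by their spots over both sections, the G2/M, fatty acid oxidation and stress medians kept their direction with different sizes. G2/M medians were below 0 in 8 of 8 regions. They ran from -0.86 in region 2 (73 and 43 spots, led by Uts2b, Vsnl1 and Sln) to -0.08 in region 1 (led by Tcf15, Sema7a and Apln). The latter lay close to the median of all genes of region 1, -0.06. Region 3 was at -0.69 and region 6 (led by Il23a, Rbp7 and Fbxo40) at -0.25, so the G2/M difference differed among the Myl2-rich regions, which was not tested. The ratio of Mki67 lay between 0.470 and 0.773 over the 8 regions, and that of Top2a between 0.545 and 0.836. The cyclin gene Ccnb1 was less even, from 0.527 in region 2 to 1.06 in region 7. Its interval lay below 1 in regions 2 and 3 only, and included 1 in the others. Fatty acid oxidation medians were -0.49, -0.52 and -0.45 in regions 1, 3 and 6, -0.17 in region 2 and -0.09, with an interval that included 0, in region 7 (32 and 34 spots, led by the cartilage collagen genes Col9a3 and Col2a1). Stress medians were above 0 in all 8 regions, from 0.65 in region 2 to 2.42 in region 3. The ratio of Nppb ran from 4.89 in region 2 to 19.1 in region 3, and that of Acta1 from 5.39 in region 5 (51 and 20 spots, led by Cyp2s1, Apela and Upk3b) to 48.6 in region 3. In region 4 (46 and 44 spots, led by Cstdc5, S100a9 and the globin gene Hba-a1) the G2/M median was -0.52, and in region 8 (14 and 24 spots, led by the mesothelial genes Upk1b and Msln) it was -0.74. S100a9 had 7 UMIs in region 4 of WT and 297 in that of the section labelled NFYa cKO. Hba-a1, which was used for the clustering that formed the region, was at 34117 and 27862 CPM. Cholesterol synthesis went both ways, from -0.57 in region 2 to 0.71 in region 6. The Nfya ratio was farthest above 1 in region 2, at 4.19 (47 and 169 UMIs, 3.02 to 5.92), and its interval included 1 in regions 5, 6, 7 and 8.

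**Figure D3:**
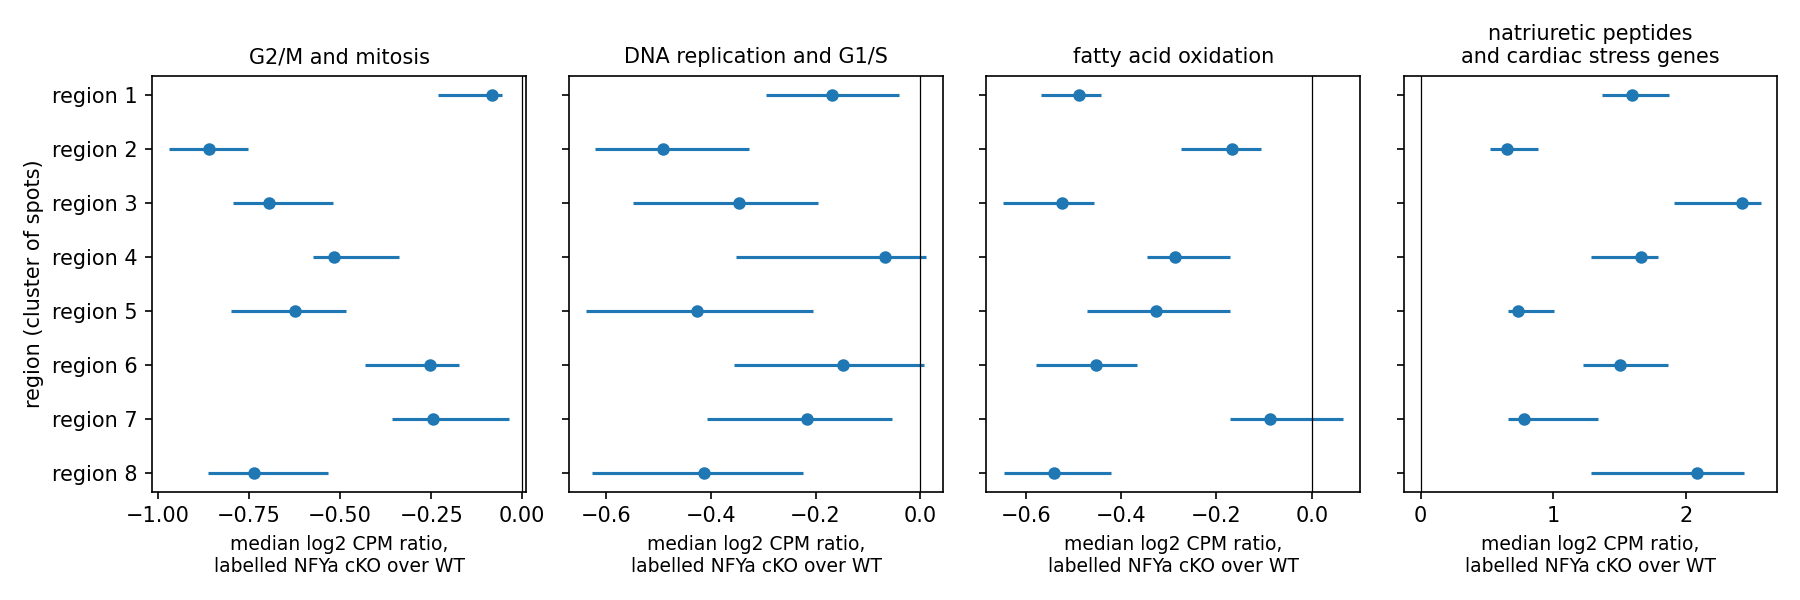
Median log2 ratio of the main gene lists in each of the 8 regions, NFYa cKO over WT, with 95% intervals from the counts. G2/M medians run from -0.86 to -0.08 and stress medians from 0.65 to 2.42.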

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

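Equal makeup of the Myl2-rich regions, all regions with Myl2 above the section mean and list members without clustering genes were tests chosen after the results were seen. In the whole section, 307 of 371 list values under alternatives stayed within the interval of the reported median, 60 moved beyond it and 4 changed the sign of a median whose interval excluded 0, and in the Myl2-rich regions the numbers were 334, 65 and 2 of 401. For named genes 116 of 120 and 236 of 250 values stayed, and 0 changed sign. Nfya stayed within its interval in both spot sets. The G2/M, G1/S, stress, calcium and fatty acid oxidation lists kept their sign under each alternative run. Centred on the median gene, whole-section medians were -0.40 (G2/M), -0.18 (G1/S) and -0.20 (fatty acid oxidation), and Myl2-rich medians -0.41, -0.22 and -0.41. That shift is the construction of the centring. At equal region makeup, fatty acid oxidation was at -0.36 and stress genes at 1.24, and the mean of spot CPM gave stress 1.24. At equal makeup of the Myl2-rich regions the medians were -0.31 (G2/M), -0.19 (G1/S), -0.48 (fatty acid oxidation) and 1.83 (stress). The trabecular list moved most among preset gene lists of the whole section, from 0.51 to 0.14 at equal makeup. In spots with Myl2 above the section median they were -0.45 (fatty acid oxidation), -0.68 (calcium) and 1.88 (stress), with clusters of variable genes -0.40 (fatty acid oxidation) and 1.90 (stress), and over all regions with Myl2 above the mean -0.45 and 1.91. Markers scaled over both sections gave -0.48 for fatty acid oxidation, but then 4 clusters took 95.8% to 100% of their spots from 1 section (114 and 5, 2 and 85, 0 and 82, 49 and 1 spots), so the match of spots between sections rests on scaling within each. Calcium genes in the Myl2-rich regions were at -0.40 with members of 100 or more UMIs, and at -0.40 without clustering genes. Among medians whose interval excluded 0, the sign changed for the mitochondrial ribosome (0.00632 after centring), histones (-0.0529 with 1 or more UMIs in each section), imprinted genes (-0.00435 at equal makeup), ventricular markers (-0.10 at equal makeup) and, in the Myl2-rich regions, ribosomal proteins (-0.0150 in spots with Myl2 above the section median, -0.00420 with clusters of variable genes). Counting medians near 0 too, 25 of 33 preset gene lists and 9 of 16 marker lists kept their sign throughout in the whole section, and 27 of 33 gene lists in the Myl2-rich regions. The others were, in the whole section, also glycolysis, mitochondrial chaperones, purine and pyrimidine synthesis, hypoxia, cardiac transcription factors, pan-endothelium, valve mesenchyme, platelets, liver, skeletal muscle and cartilage, and in the Myl2-rich regions NFY and SP factors, fatty acid synthesis, purine and pyrimidine synthesis, hypoxia and cardiac transcription factors. Apart from the centring, the cause was not tested. Depth limits small differences: in simulated counts the interval excluded 1 for 56% of genes at a fold of 0.8. No paired analysis was possible because each genotype has 1 section, and none could be left out.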

Other observations

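Tests of the G2/M list against abundant genes and against differences between embryos, and of granulocyte genes against blood, were chosen after the results were seen, as were the 4 added lists.

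Added lists of immune and contractile genes, some of which share members with the preset lists, also differed between the sections. Granulocyte genes had a median log2 ratio of 3.35 over 10 measured genes of 14 listed, all 10 higher. The calprotectin genes S100a8 and S100a9 had ratios of 9.72 and 10.6 and the stefin gene Stfa1 12.7. Members needed 20 or more UMIs over both sections together, so a gene scarce in 1 section entered by its counts in the other. Counts of higher or lower members in these immune lists are therefore not support for a difference. Genes of activated macrophages had a median of 2.01 over 9 genes, with 7 higher and 1 lower. Among them were the osteopontin gene Spp1 (8.80), the galectin gene Lgals3 (5.59) and the lysosomal gene Gpnmb (4.23), and the list shares Lpl with the fatty acid list. Mast cell genes went the other way, with a median of -3.48 over 6 genes and 5 lower (-1.16 over members with 100 or more UMIs), including the tryptase gene Tpsb2 (62 and 6 UMIs), the carboxypeptidase gene Cpa3 (0.101) and the chymase gene Cma1 (0.233). Of 20 genes responsive to myocardin-SRF or YAP, 18 were higher and 0 lower (median 1.37), with Csrp1 at 3.43, the cytokine receptor gene Tnfrsf12a at 4.06 and Thbs1 at 4.03. The median of this list in the Myl2-rich regions was 1.72, and 1.24 without clustering genes. Acta1, Ankrd1, Ccn1 and Ccn2 are in this list and in the stress list, and Tagln is also a preset smooth muscle marker. Since the 4 added lists were chosen after the results were seen, their medians are not separate observations.

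Globin genes split by age of expression. The adult-type genes Hbb-bs and Hba-a1, each with a near-identical copy, had ratios of 0.653 and 0.678. The embryonic genes Hbb-y (28.9 and 51.0 CPM, ratio 1.77, 1.53 to 2.05), Hba-x (1.70) and Hbb-bh1 (2 and 28 UMIs, 10.6) were higher in the section labelled NFYa cKO. Agtr2, nearly missing there, had its 225 WT UMIs in 57 of 373 spots, with 80% in 19 spots. The chemokine gene Cxcl13, chosen outside the naming rule after its values were seen, had 90 UMIs in WT and 1 in the section labelled NFYa cKO (ratio 0.00840, 0.000211 to 0.0480).

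Nfya was higher in the section labelled NFYa cKO. Unequal shares of the regions are argued against as the whole cause, because the log2 ratio was 0.78 with both sections weighted to the same region makeup. Makeup inside a region stays open, because regions were matched by scaling within each section and marker levels were not held equal. Tags from outside the deleted part stay open, since the ratio of 1.605 in the Myl2-rich regions carries no information on a deletion whose position is not given. Exchanged labels could not be examined, because 0 sections had more Xist than Y-linked UMIs and embryo sex therefore does not tell the sections apart. A biological difference in Nfya transcription between the genotypes was not tested.

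G2/M genes were lower in the section labelled NFYa cKO. Unequal shares of the regions as the whole cause are argued against by the makeup-weighted median of -0.47 (-0.50 to -0.39). Medians were also below 0 in 8 of 8 regions, although in region 1 the median of -0.08 was close to that of all genes, -0.06. Tissue makeup inside a region stays open here too, since marker levels were not held equal. An excess of counts in a few abundant genes is argued against by the list median, -0.40 relative to the median of all genes. With 1 section per genotype, a difference between embryos or sections, stage included, cannot be told apart from genotype. The same holds for all other lists, the metabolic, stress, calcium handling and sarcomere lists included. The globin genes leave a difference in stage open for each of them. A link of the G2/M genes to NF-Y was not tested.

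Granulocyte genes were higher in the section labelled NFYa cKO. The erythroid list, with a median of -0.53 (-0.54 to -0.51), showed no excess that would go with more blood in the section. Of its 10 measured genes, however, 3 were higher and 6 lower, and globin genes split by age of expression. A difference in stage could move this median without a difference in blood, so the list does not settle the amount of blood. A local deposit stays open: 76.5% of its 857 S100a8 and S100a9 UMIs lay in 17 of 333 spots, between the preset bounds, while 123 spots held at least 1. Region 4, rich in globin UMIs in both sections, held 65.7% of them in 44 spots. In WT that region held 5 S100a8 and 7 S100a9 UMIs. The erythroid median covers the whole section, so it does not tell whether the UMIs of region 4 came from blood there. Recruitment of granulocytes by the genotype was not tested.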
